A study of Homo sapiens with 4 samples.

How the data were processed

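The study measured mRNA of HCT116 cells, a human colon cancer line, by RNA sequencing in 4 libraries, 2 of cells given DMSO and 2 of cells given N_12 for 24 h in medium with 10% serum. Libraries were built from 1.4 ug of total RNA each with a kit for mRNA, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The treatment tag of the N_12 samples carries a different compound code (HJJ_3_5), the dose is not given in the labels, and N_12 is a code name whose structure was not examined. The values deposited by the authors are whole-number counts per gene, with no normalization, in a single table keyed by human Ensembl gene identifiers. The aligner, the counting tool and the strand setting are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10, which does not match the human identifiers in the table, so no genomic coordinates are printed. Without a stated strand setting, reads from overlapping genes cannot be told apart.

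Symbols were assigned to 20148 of the 20263 identifiers and 115 had none; 3554 genes had 0 counts in every library, and no row named anything other than a gene. Gene lengths, GC content and exon overlap came from GENCODE release 29 and were known for 14089 of the 14105 tested genes. Total counts ranged from 29769568 to 41717938 per library, and the 10 genes with most counts took 9.65% to 11.1% of them. The biological coefficient of variation estimated over all genes was 0.182.

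Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM (factors 0.98 to 1.02), genes were kept by edgeR's expression filter with the groups given, and a quasi-likelihood model with robust dispersion estimates and no replicate term compared N_12 with DMSO. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all tested genes, two-sided. Genes counted as rising or falling are those called at this threshold, and genes not called may lie on the same side of 0. CPM values of single genes use TMM-scaled totals, standard errors were obtained from the fold change and the F statistic, and intervals are 95% intervals. With 2 libraries per group, complete separation of the groups arises by chance for 33.3% of genes and so carries little weight on its own.

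Before the data were examined, 33 gene lists, the model and the other settings to be tried were written down. The lists cover mesenchymal and epithelial markers, adhesion and migration, G1/S and replication, mitosis, replication histones, p53 targets, ATF4 targets, endoplasmic reticulum chaperones, heat shock, NRF2 and aryl hydrocarbon receptor targets, NF-kB, interferon, pro- and anti-apoptotic genes, immediate-early genes, ERK, Wnt, YAP and TGF-beta outputs, ribosome biogenesis, ribosomal proteins, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded genes, cholesterol and fatty acid synthesis, lysosome and autophagy, colonocyte differentiation, kinases bound by nilotinib, and markers of fibroblasts, leukocytes and endothelial cells. Lists with at least 3 tested members (32) were tested with camera of limma 3.58.1 at its preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. The genes named by rule were the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM, a symbol and groups that do not overlap. To these the rule added a panel of EMT, proliferation and drug target genes (CDH1, CDH2, VIM, FN1, SNAI1, SNAI2, ZEB1, EPCAM, MKI67, PCNA, CCND1, MYC, CDKN1A, ABL1 and DDR1), up to 4 members of each list with the smallest p, and up to 4 abundant genes of each list of another cell type as values. Members chosen by that last clause are named where they serve as examples; MARS1 and H2AC6 lie outside the rule and were named to complete counts of 5.

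The procedure was tested on simulated data with the means and depths of this comparison, in a step on 13965 genes. Of 50 genes simulated at each of 1.5-, 2-, 4- and 8-fold, 3, 29, 47 and 49 were called, 0 of them in the wrong direction. Of all 148 calls, 20 were genes simulated without a change. This is a larger share than the threshold is meant to allow, so the threshold was not kept in this step. A raised list was called and 0 of 20 unchanged lists were. This does not show how the list test behaves for strongly correlated members, as estimated for some of the real lists.

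Replicates were compared before use. Their counts differed by far more than sampling noise (chi-square per degree of freedom 36.5 for DMSO and 57.2 for N_12), so all 4 libraries were counted separately. Spearman's correlation across genes, which are not independent replicates, was 0.986 between the DMSO libraries and 0.984 between the N_12 libraries. Alternatives planned beforehand were other scalings, other filters, a term for the replicate number, leaving out each library, limma-voom, DESeq2 1.42.0, non-robust dispersions and a minimum fold of 1.5. Corrections of each library for its trend with GC content and length, by a spline with 5 degrees of freedom, were added after seeing the data. All libraries and every column of the table were used.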

Results

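HCT116, an established human colon cancer cell line, was grown for 24 h with the compound N_12 or with its solvent DMSO, and mRNA libraries were sequenced. The series title describes N_12 as a derivative of nilotinib, a kinase inhibitor directed at BCR-ABL, and names proliferation, migration and the epithelial to mesenchymal transition (EMT). Each group held 2 libraries, with total counts of 31120459 and 29769568 for DMSO replicates 1 and 2 and of 41717938 and 39865327 for N_12 replicates 1 and 2. The table listed 20263 genes, of which 14105 had enough counts to be tested. Because the labels do not say whether replicates came from separate cultures, p-values of single genes measure only the spread between these samples, which may be technical. List p-values with the preset correlation instead compare members with other genes, taken as nearly independent (0.01). Estimated correlations were near that for some lists (0.015 for G1/S and replication). For others they were far above it (0.141 for glycolysis and hypoxia, 0.264 for ribosomal proteins, 0.733 for mitochondrially encoded genes).

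The comparison of N_12 with DMSO asked which transcripts differed after 24 h of treatment, with attention to EMT, migration and proliferation. Of 38 tested genes of glycolysis and of the hypoxia response, 22 were called lower in N_12, none was called higher, and the median log2 fold change was -0.90 (list adjusted p = 1.83e-61 with a preset correlation and adjusted p = 0.314 with an estimated correlation). Among them ANKRD37, a target of the hypoxia-inducible factor HIF, fell 9.97-fold, from 59.3 ± 14.4 to 5.95 ± 1.23 CPM (counts scaled to library size, mean ± SD, n = 2 per group), and HK2, a hexokinase gene of the first step of glycolysis, fell 3.63-fold, from 228 ± 32.8 to 62.7 ± 7.65 CPM. Ribosomal protein genes fell in 26 of 67 cases (median -0.64), and immediate-early genes such as FOS and EGR1 fell in 7 of 24; without DMSO replicate 1 these counts were 9 and 3. In the other direction, ATF5, a transcription factor of the stress response to amino acid shortage, rose 5.84-fold, from 3.17 ± 0.20 to 18.5 ± 0.833 CPM. Of the fixed panel of EMT, proliferation and drug target genes only MYC was called, as lower. That call did not hold without DMSO replicate 1, where its log2 fold change was -0.92. The other panel genes were not thereby shown to be unchanged. Intervals of the log2 fold change lay wholly on the lower side for CDH1 (-0.92 to -0.11), EPCAM (-0.75 to -0.09) and DDR1 (-0.78 to -0.08). That of ZEB1 (0.18 to 1.34) lay on the higher side, and those of the other tested panel genes included both signs.

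In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 317 of 14105 genes (2.25%), 116 higher and 201 lower in N_12, and 3079 genes had an unadjusted p under 0.05. The split of 36.6% higher calls became 46.2% when libraries were scaled by their totals alone. Without N_12 replicate 1, or without N_12 replicate 2, no gene was called by edgeR, although 2855 and 2761 genes had an unadjusted p under 0.05. On all 4 libraries limma-voom called 131 genes and DESeq2 1225. Of the 87 called genes among the 110 tested genes named in the text, 24 lost the call without DMSO replicate 1, 16 without DMSO replicate 2 and 30 with limma-voom.

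The largest fall among called genes with a mean of at least 5 CPM was that of ARRDC4 (ENSG00000140450), an alpha-arrestin whose transcription follows glucose. It went from 381 ± 6.09 to 25.7 ± 2.49 CPM, a log2 fold change of -3.89 (SE 0.15, adjusted p = 9.72e-05). Several of the next genes are induced by low oxygen. These were ANKRD37 (ENSG00000186352, -3.32, SE 0.25), the lipid droplet protein gene HILPDA (ENSG00000135245, -2.94, SE 0.22), the peptide hormone gene ADM (ENSG00000148926, -2.30, SE 0.18), the lipoprotein lipase inhibitor ANGPTL4 (ENSG00000167772, -2.01, SE 0.17) and the aldolase gene ALDOC (ENSG00000109107, -1.92, SE 0.15). A pair of genes of protein palmitoylation, GOLGA7B (-2.88, SE 0.20) and ZDHHC20 (-2.19, SE 0.21), also fell. The remaining falls were those of the Mediator subunit MED29 (-2.66, SE 0.21), the TNF-family ligand EDA (-2.43, SE 0.21), CCDC117 (-2.16, SE 0.24) and the zinc finger gene PLAG1 (-1.96, SE 0.20). Adjusted p-values of these 12 genes lay at or below 0.0106. Both N_12 libraries lay below both DMSO libraries for each, which the rule for naming genes required.

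**Figure D1:**
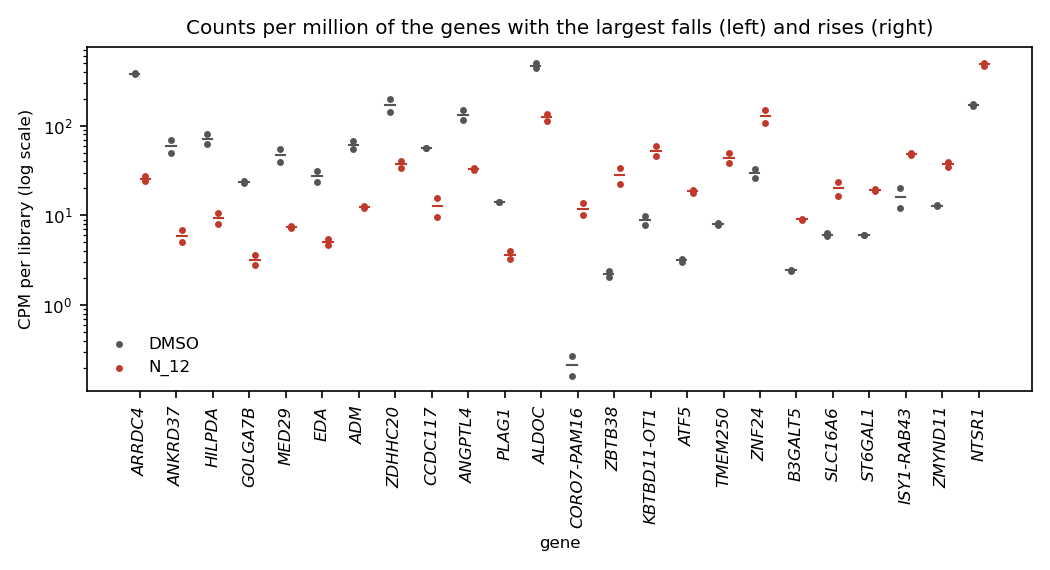
CPM (log scale) in each library for the 12 genes with the largest falls and the 12 with the largest rises among called genes, with DMSO in grey and N_12 in red, points for libraries and short lines for group means. The rule for naming these genes required the N_12 points to lie on 1 side of both DMSO points. Examples are ARRDC4 at 377 and 386 against 27.4 and 23.9 CPM and NTSR1 at 165 and 173 against 460 and 505 CPM.

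Among the rises, CORO7-PAM16 (ENSG00000103426) had the highest log2 fold change, 5.76 (SE 0.34), from 0.218 ± 0.0764 to 11.9 ± 2.69 CPM. This is a read-through gene all of whose exon bases (100%) are shared with CORO7 and PAM16, so its value depends on how reads were assigned. The same holds for ISY1-RAB43 (1.59, SE 0.26), and KBTBD11-OT1 (2.57, SE 0.21) lies wholly on exons of ARHGEF10 and CLN8. The methyl-DNA-binding zinc finger gene ZBTB38 (ENSG00000177311, 3.67, SE 0.26), ATF5 (ENSG00000169136, 2.55, SE 0.19), TMEM250 (2.44, SE 0.19) and the zinc finger gene ZNF24 (2.11, SE 0.21) rose as well. They share no exon bases with other listed genes on the same strand, while overlap on the other strand was not examined. Also higher were the glycosyltransferases B3GALT5 (1.89, SE 0.20) and ST6GAL1 (1.65, SE 0.18), the monocarboxylate transporter family member SLC16A6 (1.73, SE 0.22), the histone reader ZMYND11 (1.53, SE 0.16) and the neurotensin receptor NTSR1 (ENSG00000101188, 1.51, SE 0.13). The adjusted p-values of these 12 genes ranged up to 0.0357. NTSR1 was the most abundant of them, at 169 ± 6.10 CPM in DMSO and 482 ± 31.3 CPM in N_12.

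Single EMT markers of the panel were not called. CDH1, the E-cadherin of epithelial junctions, stood at 80.5 ± 7.51 CPM in DMSO and 56.3 ± 10.7 CPM in N_12 (log2 fold change -0.52, 95% interval -0.92 to -0.11, adjusted p = 0.151), and EPCAM at 264 ± 16.6 and 198 ± 24.6 CPM (-0.42, adjusted p = 0.152). The mesenchymal filament gene VIM had a log2 fold change of 0.07 (-0.28 to 0.42) and the matrix gene FN1 of -0.19 (-0.60 to 0.22). Of the EMT transcription factors, SNAI1 differed by -0.07 (-0.44 to 0.29), SNAI2 by 0.22 (-0.44 to 0.88) and ZEB1 by 0.76 (0.18 to 1.34, adjusted p = 0.143). CDH2, the N-cadherin gene, had counts of 0 and 4 in DMSO and of 2 and 0 in N_12, too few for a test. THBS1, a matrix glycoprotein gene of the mesenchymal list, fell (-1.10, SE 0.21, adjusted p = 0.0464). Of 38 tested members edgeR called it alone over all genes, DESeq2 called 5 and limma-voom 0 (THBS1 adjusted p = 0.0754), while 1 higher and 2 lower members were called when adjusted over the list alone. In the epithelial list ELF3, an epithelial ETS factor (-1.14, SE 0.15, adjusted p = 0.0155), and AP1M2, a basolateral sorting adaptor (-0.79, SE 0.16, adjusted p = 0.0495), fell. By edgeR the other 49 of 51 members passed neither over all genes nor adjusted over the list alone, whereas DESeq2 called 7 members, limma-voom 1 and edgeR with GC correction 1 higher and 6 lower. Among 48 adhesion and migration genes edgeR called only the syndecan gene SDC4, which fell (-1.10, SE 0.14, adjusted p = 0.0122), and adjusted over the list alone 1 was higher and 3 were lower. DESeq2 called 6 of them, limma-voom 1, and edgeR with GC correction 3 higher and 4 lower. Camera with the preset correlation called none of these lists, with adjusted p = 0.764 for the mesenchymal, 0.107 for the epithelial (median -0.10) and 0.966 for the adhesion and migration list. Fry's mixed test, which asks whether genes of a list change in either direction, passed for each (adjusted p = 0.0306, 0.0246 and 0.0177). It passed for 27 of the 32 tested lists, so this is not particular to EMT or migration. A correction for GC content and length moved the epithelial list past the threshold, to lower (adjusted p = 0.0225, median log2 fold change -0.16), with adjusted p = 0.415 under that correction with an estimated correlation. Leaving out N_12 replicate 2 did so as well (adjusted p = 0.0324, median -0.19), whereas without N_12 replicate 1 the median was -0.03 (adjusted p = 0.451). THBS1 (adjusted p = 0.0932) and AP1M2 (0.203) lost their calls without DMSO replicate 1, and AP1M2 did without DMSO replicate 2 (0.0739). Without the latter library 2 mesenchymal genes were called higher and 2 lower, and 1 gene of the adhesion and migration list was called higher. In the epithelial list 1 gene was called higher when either DMSO library was left out.

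**Figure D2:**
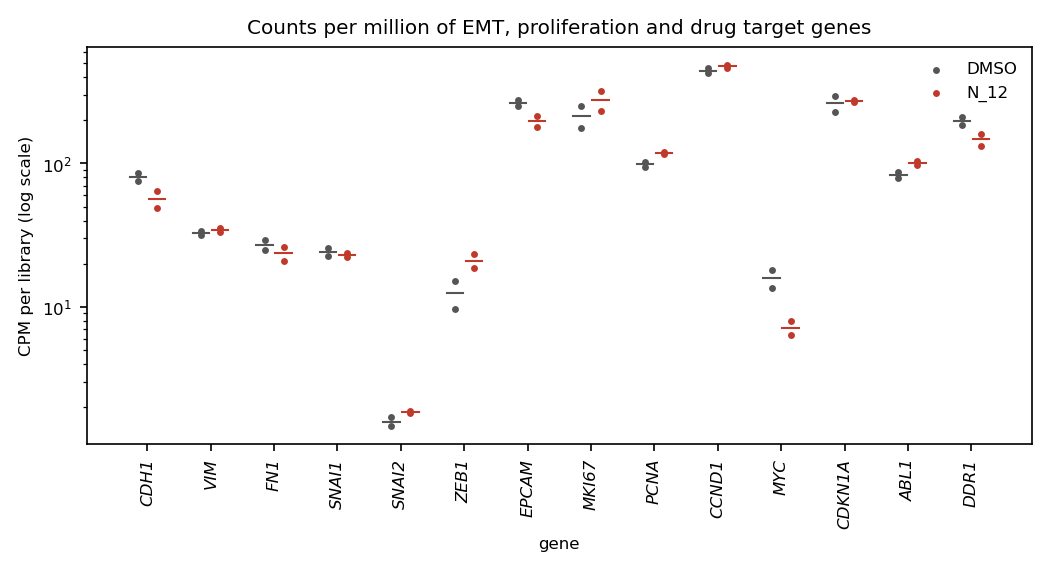
CPM (log scale) in each library for the tested genes of the fixed panel, with DMSO in grey and N_12 in red, points for libraries and short lines for group means. MYC, at 18.0 and 13.6 against 7.95 and 6.38 CPM, was the only gene of the panel called with all 4 libraries, a call that ended without DMSO replicate 1.

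MYC, a driver of cell growth, fell from 15.8 ± 3.11 to 7.16 ± 1.11 CPM (log2 fold change -1.14, SE 0.22, adjusted p = 0.0441). Its log2 fold change was -0.92 without DMSO replicate 1 (adjusted p = 0.133), and limma-voom did not call it (adjusted p = 0.0743). The G1/S and replication list was higher, with a median of 0.27, adjusted p = 4.84e-07 with the preset correlation of camera and adjusted p = 0.314 with an estimated correlation. Of its 58 genes 48 lay above 0 and 3 were called higher, the helicase genes MCM5 (0.86, SE 0.14) and MCM3 (0.72, SE 0.14) and the transcription factor E2F1 (0.95, SE 0.17). Adjusted over the list alone, 13 were higher and 0 lower. Without DMSO replicate 1 none of the 3 was called (adjusted p from 0.0520 to 0.157) and 1 other member was called lower, and without DMSO replicate 2 these 3 were again not called (0.0632 for MCM5, the lowest of them) although 3 members were called higher. On all 4 libraries limma-voom called 0 members, DESeq2 12 and edgeR with GC correction 9 higher. For the mitosis list the median was 0.24, with 45 of 56 genes above 0. MYBL2 alone was called higher (0.76, SE 0.14, 1 adjusted over the list alone). The test gave adjusted p = 0.000703 preset and adjusted p = 0.52 with an estimated correlation. The mitosis call ended without DMSO replicate 1 (adjusted p = 0.152) and without N_12 replicate 1 (adjusted p = 0.0698). Its median was 0.07 without DMSO replicate 1, 0.38 without DMSO replicate 2 and 0.14 without N_12 replicate 1. MYBL2 lost its call when either DMSO library was left out (adjusted p = 0.0981 and 0.103) and with limma-voom, while 5 members were called higher without DMSO replicate 2, 4 with GC correction and 3 by DESeq2. Marker genes gave MKI67 0.36 (-0.19 to 0.91), PCNA 0.27 (-0.04 to 0.57), CCND1 0.10 (-0.19 to 0.39) and the cell cycle inhibitor CDKN1A 0.06 (-0.29 to 0.41), none of them called. Replication-dependent histone genes, which have near-identical copies and so uncertain counts, were called lower in 5 of 12 cases (H1-2 -1.70, H2BC4 -2.25, H2BC21 -1.52, H2AC6 -1.24 and H2BC5 -1.11). How the kit for mRNA captured histone transcripts was not examined, so their fall is not read as a measure of replication. H2BC5 lost its call without DMSO replicate 1 (adjusted p = 0.0591) and H2AC6 without DMSO replicate 2 (0.0712). The median of the histone list, -0.75, became -0.39 with GC and length correction and -1.24 over the 7 genes left by a stricter filter. DESeq2 called 5 members and limma-voom 3. Of its 12 genes 5 also fell adjusted over the list alone, with adjusted p = 4.36e-07 preset and adjusted p = 0.314 with an estimated correlation.

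The glycolysis and hypoxia list had the smallest p of the 32 tested lists with the preset correlation (adjusted p = 1.83e-61), and adjusted p = 0.314 with an estimated correlation. All 38 tested members had a negative log2 fold change. Of these, 22 were called lower over all genes and 31 adjusted over the list alone. DESeq2 called 25 and limma-voom 16. Its 15 glycolytic enzymes included 7 called lower (median -0.87), and 15 of the other 23 members were called lower (median -0.94). The glucose transporter SLC2A3 went from 353 ± 1.25 to 115 ± 7.44 CPM (-1.62, SE 0.13, adjusted p = 0.00201), and PGK1, which makes ATP in glycolysis, had a log2 fold change of -1.53 (SE 0.13). GAPDH, often used as a reference gene, fell from 14726 ± 1587 to 7606 ± 363 CPM (-0.95, SE 0.15, adjusted p = 0.0237). The oxygen sensor gene EGLN1, itself a HIF target, fell as well (-0.84, SE 0.16, adjusted p = 0.0413), a call that ended without DMSO replicate 1 (adjusted p = 0.124). Neither limma-voom (adjusted p = 0.0730) nor edgeR without robust dispersions (0.0768) called EGLN1. EGLN1, PGK1, GAPDH and HK2 were named after their values were seen.

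**Figure D3:**
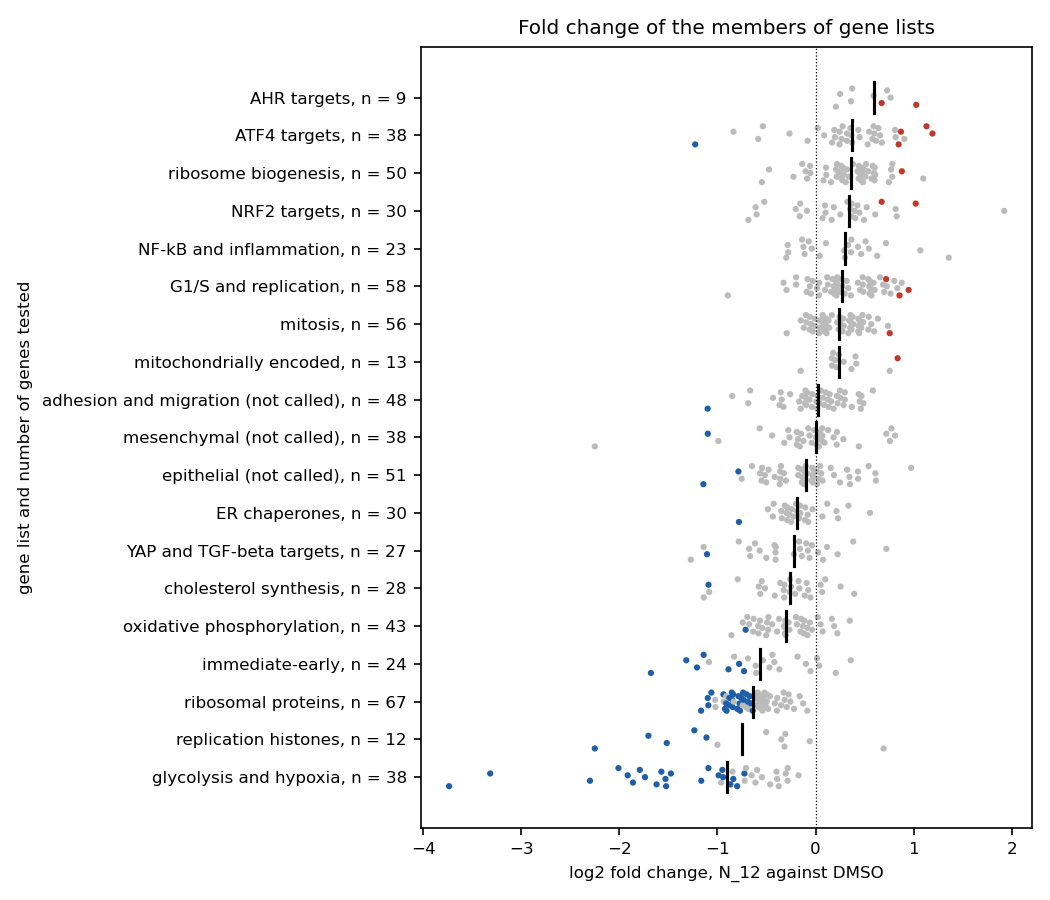
Log2 fold change of each tested gene (points) in the 16 lists called with the preset correlation and in the epithelial, mesenchymal and adhesion lists, with list medians as black bars, genes called lower in blue, genes called higher in red and genes not called in grey. The medians run from -0.90 for glycolysis and hypoxia to 0.59 for targets of the aryl hydrocarbon receptor.

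Genes of translation split. All 67 ribosomal protein genes tested had a negative log2 fold change, and 26 were called lower over all genes and 58 adjusted over the list alone. Over all genes 9 fell without DMSO replicate 1, 6 with limma-voom and 44 with GC correction, and DESeq2 called 54. Examples were RPL34 (-1.17, SE 0.13, adjusted p = 0.00747), RPL23 (-0.94, SE 0.13), RPL31 (-1.10, SE 0.15) and RPL21 (-0.84, SE 0.12). Pseudogene copies of these genes make their counts uncertain. The list test gave adjusted p = 8.62e-43 preset and adjusted p = 0.314 with an estimated correlation. Ribosome biogenesis genes lay higher (median 0.36, adjusted p = 4.84e-07 preset and adjusted p = 0.314 with an estimated correlation), with 42 of 50 above 0. MYBBP1A (0.88, SE 0.16) was the 1 gene called higher. Without DMSO replicate 1 the list held 0 called genes and without DMSO replicate 2 it held 3, with MYBBP1A in neither case (adjusted p = 0.0625 without DMSO replicate 1). On all 4 libraries limma-voom called 0 members, DESeq2 12 and edgeR with GC correction 10 higher and 1 lower. Adjusted over the list alone, 16 were higher and 1 lower.

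Stress responses went in different directions. Of 38 ATF4 targets, genes of the integrated stress response, the serine synthesis enzyme PSAT1 (1.13, SE 0.14), the pseudokinase TRIB3 (1.19, SE 0.16), the asparagine synthetase ASNS (0.85, SE 0.13) and the tRNA synthetase MARS1 (0.87, SE 0.14) rose. DDIT4, which is also induced by low oxygen, fell (-1.23, SE 0.18). Adjusted over the list alone 16 were higher and 3 lower. The median was 0.37, and the list had adjusted p = 1.18e-07 preset and adjusted p = 0.392 with an estimated correlation. The NRF2 list was higher (median 0.34, adjusted p = 0.000568 preset and adjusted p = 0.314 with an estimated correlation). Of its 30 genes 2 were called higher, thioredoxin reductase TXNRD1 (1.02, SE 0.13) and the quinone reductase NQO1 (0.67, SE 0.12), and 9 were higher and 1 lower adjusted over the list alone. With GC correction edgeR called 7 NRF2 targets higher and 1 lower, and 13 ATF4 targets higher and 2 lower. NQO1 and the receptor repressor AHRR (1.03, SE 0.16) rose among 9 targets of the aryl hydrocarbon receptor (median 0.59, 4 higher adjusted over the list alone), with adjusted p = 0.000754 preset and adjusted p = 0.314 with an estimated correlation. Chaperones of the endoplasmic reticulum lay lower (median -0.19, adjusted p = 0.0457 preset and adjusted p = 0.52 with an estimated correlation), with 24 of 30 genes below 0. HSPA5 was the 1 gene called lower (-0.78, SE 0.14, with 1 higher and 1 lower adjusted over the list alone). The NF-kB list (median 0.30, adjusted p = 0.048 preset and adjusted p = 0.463 with an estimated correlation) had 0 of 23 genes called by edgeR, 7 with an unadjusted p under 0.05, 1 higher adjusted over the list alone, 1 called by DESeq2 and 0 by limma-voom. Its lowest p was that of NFKB1 (0.72, SE 0.15, adjusted p = 0.0535). The NF-kB call ended without any 1 library (adjusted p from 0.0781 to 0.183), and the median was 0.17 without N_12 replicate 1 and 0.14 without N_12 replicate 2. The chaperone call ended without DMSO replicate 1 (0.223, median -0.13), N_12 replicate 1 (0.0516) or N_12 replicate 2 (0.0983). Among the genes, HSPA5 (adjusted p = 0.117) and NQO1 (0.0882) lost their calls without DMSO replicate 1, and NQO1 (0.109), AHRR (0.0630) and MARS1 (0.0598) without DMSO replicate 2, when 3 ATF4 targets were called lower. Of ATF4 targets, NRF2 targets, targets of the aryl hydrocarbon receptor and chaperones, DESeq2 called 17, 8, 3 and 2 and limma-voom 4, 1, 1 and 0, without MARS1, NQO1 and HSPA5 (adjusted p = 0.0577, 0.0644 and 0.0634).

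Immediate-early genes were called lower in 7 of 24 cases, with 12 lower and 1 higher adjusted over the list alone (median -0.57, adjusted p = 3.26e-09 preset and adjusted p = 0.47 with an estimated correlation). FOS went from 33.7 ± 1.02 to 10.5 ± 0.540 CPM (-1.68, SE 0.16, adjusted p = 0.00427), EGR1 from 619 ± 73.8 to 248 ± 6.84 CPM (-1.32, SE 0.14), and DUSP1 (-1.21, SE 0.17) and JUN (-0.78, SE 0.14) fell too. The list of ERK outputs was not called by camera (adjusted p = 0.449). The ERK phosphatase DUSP4 (0.70, SE 0.12) and the feedback inhibitor SPRY1 (1.16, SE 0.20) rose while FOS, EGR1 and MYC fell. Adjusted over the list alone, 4 of 28 were higher and 7 lower. YAP and TGF-beta targets lay lower (median -0.22, adjusted p = 0.00855 preset and adjusted p = 0.52 with an estimated correlation), with 21 of 27 genes below 0. GADD45B was the 1 gene called lower (-1.11, SE 0.16, with 1 higher and 5 lower adjusted over the list alone). That list call ended without N_12 replicate 1 (adjusted p = 0.0622). Called members numbered 2 lower without DMSO replicate 1, and 1 higher and 2 lower without DMSO replicate 2. The immediate-early list held 3 lower genes and 1 higher without DMSO replicate 1, where JUN lost its call (adjusted p = 0.168). DUSP4 and SPRY1 lost theirs without DMSO replicate 1 (0.0943 and 0.0797) and without DMSO replicate 2 (0.0732 and 0.0686). Of immediate-early genes, ERK outputs and YAP and TGF-beta targets, DESeq2 called 8, 10 and 7 and limma-voom 3, 2 and 1, without JUN, DUSP4 and SPRY1 (adjusted p = 0.0719, 0.0527 and 0.0629).

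In metabolism, cholesterol synthesis genes lay lower (median -0.26, adjusted p = 3.81e-05 preset and adjusted p = 0.47 with an estimated correlation), with 23 of 28 genes below 0. The sterol-responsive gene INSIG1 was the 1 gene called lower (-1.09, SE 0.13, with 5 lower adjusted over the list alone). Nuclear genes of oxidative phosphorylation lay lower as well (median -0.31, adjusted p = 2.98e-06 preset and adjusted p = 0.47 with an estimated correlation). Of these 43 genes 36 lay below 0, NDUFA4 was the 1 called lower (-0.71, SE 0.14), and 8 were lower adjusted over the list alone. The mitochondrially encoded genes were higher (median 0.24, adjusted p = 0.0017 preset and adjusted p = 0.52 with an estimated correlation), with 12 of 13 above 0. MT-ND1 was the 1 gene called higher (0.84, SE 0.17, with 2 higher adjusted over the list alone). The mitochondrially encoded call ended without DMSO replicate 1 (adjusted p = 0.0562) and without N_12 replicate 1 (0.435). Its median ranged from 0.16 without N_12 replicate 1 to 0.38 without N_12 replicate 2 and was 0.57 with GC and length correction. MT-ND1 lost its call without DMSO replicate 1 (0.114), and 2 members were called higher without DMSO replicate 2. The oxidative phosphorylation median was -0.20 both without DMSO replicate 1 and with GC and length correction, and NDUFA4 lost its call when either DMSO library was left out (adjusted p = 0.194 and 0.0603). Limma-voom called 0 genes of the oxidative phosphorylation and mitochondrially encoded lists. DESeq2 called 10 and 2 of them. In the cholesterol list 2 genes were called lower without DMSO replicate 2, and DESeq2 called 6 and limma-voom 1. Mitochondrially encoded transcripts took 6.59% and 7.73% of counts in the DMSO libraries and 9.61% and 8.23% in the N_12 libraries.

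The other lists were not called by camera. Among p53 targets (adjusted p = 0.711) the stress cytokine GDF15 (1.27, SE 0.13, adjusted p = 0.00605) and the death gene BBC3 (1.29, SE 0.19, adjusted p = 0.0211) rose, with 3 higher and 1 lower of 37 adjusted over the list alone. Pro-apoptotic genes (adjusted p = 0.413) held BBC3 on the higher side and BNIP3L (-0.80, SE 0.14) and BMF (-0.89, SE 0.17) on the lower, with 2 higher and 3 lower of 26 adjusted over the list alone. The Wnt target list (adjusted p = 0.344) had SOX4 (-1.09, SE 0.15) and MYC lower, 2 of 23 also adjusted over the list alone. In the heat shock list (adjusted p = 0.408) HSPH1 rose (1.01, SE 0.16) and DNAJB1 fell (-0.93, SE 0.13), 1 each also adjusted over the list alone. Without DMSO replicate 1, BMF (adjusted p = 0.177) and HSPH1 (0.0747) lost their calls, and without DMSO replicate 2 BNIP3L (0.0772) and BMF (0.0597) did. Of p53 targets, pro-apoptotic genes, Wnt targets and heat shock genes, DESeq2 called 5, 4, 4 and 4 and limma-voom 1, 0, 1 and 1, without BBC3 (adjusted p = 0.0503), BNIP3L (0.0660), BMF (0.0726), HSPH1 (0.0517) and MYC. In 6 lists edgeR called no gene over all genes on all 4 libraries, and limma-voom none either. These were fatty acid synthesis (list adjusted p = 0.408), with 2 of 17 genes higher and 1 lower adjusted over the list alone, 6 at an unadjusted p under 0.05 and 3 called by DESeq2, and lysosome and autophagy (0.408), with 0 of 40, 10 and 7. The interferon list (0.518) had 1 of 33 higher and 4 lower adjusted over the list alone, 13 at an unadjusted p under 0.05 and 7 called by DESeq2, and colonocyte differentiation (0.373) had 1 of 11 lower, 3 and 1. Anti-apoptotic genes (0.763) had 0 of 12 adjusted over the list alone, 2 at an unadjusted p under 0.05 and 1 called by DESeq2, and kinases bound by nilotinib (0.905) had 0 of 10, 1 and 0. Without DMSO replicate 2 edgeR called 1 interferon gene higher and 1 lower and 1 anti-apoptotic gene higher. With GC correction it called 2 higher and 3 lower in the interferon list and in the lysosome and autophagy list, 1 higher and 1 lower in fatty acid synthesis, 1 lower each among anti-apoptotic and colonocyte genes, and 0 of the nilotinib kinases. Among those kinases, ABL1 had a log2 fold change of 0.27 (-0.05 to 0.58) and DDR1 of -0.43 (-0.78 to -0.08, adjusted p = 0.159).

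The lists also covered markers of cell types other than the studied line. COL1A1 stood at 63.2 and 60.1 CPM of the unscaled library total in DMSO and at 55.6 and 61.3 in N_12, CD68 at 40.4 and 34.2 against 48.7 and 42.7, and EGFL7 at 96.2 and 86.4 against 87.7 and 109. Next came CD74, at 1.16 and 1.65 in DMSO and 2.40 and 3.31 in N_12. The highest value in any library was 1.78 for VWF, 0.705 for KDR, 0.407 for CD14, 0.336 for LYZ, 0.216 for COL3A1, 0.176 for CLDN5, 0.151 for THY1 and 0.144 for FAP. No marker was called over all genes by edgeR, DESeq2 or limma-voom, and 1 of the 3 tested leukocyte markers had an unadjusted p under 0.05 and was higher adjusted over the list alone. The leukocyte list had adjusted p = 0.0874 and the endothelial list 0.906, while the fibroblast list had only 1 tested gene and so no list test.

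Camera called 16 of the 32 tested lists with its preset correlation, 8 lower and 8 higher, and 0 with an estimated correlation, where 0.314 was the lowest adjusted p and 2 lists had an unadjusted p under 0.05. With 2 libraries per group even the glycolysis and hypoxia list, all 38 members of which were lower, had an unadjusted p of 0.0156 there. A lack of calls with the estimated correlation therefore decides little. Fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, called 0 lists after adjustment (14 had an unadjusted p under 0.05), and its mixed test, which asks whether they change in either direction, called 27. Median, mean and test differed in sign for 5 lists: the mesenchymal (median 0.0070, mean -0.06, test lower), adhesion and migration (0.03, -0.0043, lower), ERK output (0.04, -0.05, lower), endothelial (0.06, -0.07, lower) and anti-apoptotic lists (0.04, 0.0091, lower).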

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

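The corrections for GC content and length were chosen after seeing the data; the other alternatives were planned. The 317 calls (116 higher, 201 lower) became 321 with RLE factors, 321 with upper quartile scaling, 305 with library totals alone, 367 without a filter and 394 with a stricter one. They became 131 (47 higher, 84 lower) with limma-voom, of which 129 were shared, and 131 (47, 84) without robust dispersions, of which 130 were shared. DESeq2 called 1225 (551, 674), including 309 of the 317, and a test against a minimum fold of 1.5 called 47 (13, 34). Differences between replicates followed GC content across genes (Spearman's rho 0.351 for DMSO, -0.58 for N_12). Correcting each library for that trend gave 1056 (476, 580), and for GC and length 931 (416, 515), of which 298 were shared. Same-numbered libraries did not deviate together (correlation -0.0895) and the labels do not pair them. With the replicate number as a block 964 genes (439, 525) were called, all 317 among them, and with the block plus GC and length correction 106 (37, 69). The block leaves fewer degrees of freedom to estimate the spread of each gene, so the larger count is not read as a gain in sensitivity. Under the block NF-kB lost its list call (adjusted p = 0.0788), and called members rose to 3 higher and 3 lower in the mesenchymal list, 2 and 4 in the epithelial, 1 and 4 in the adhesion, 13 and 3 in the ATF4, 2 and 4 in the interferon, 6 and 1 in the ribosome biogenesis, 1 and 3 in the YAP and TGF-beta and 0 and 2 in the anti-apoptotic list. They rose to 10 higher in G1/S, 4 in NRF2, 3 in mitosis and 2 in NF-kB and mitochondrially encoded genes, and to 39 lower in ribosomal proteins (0 with the correction added), 7 in oxidative phosphorylation, 5 in cholesterol and 2 in colonocyte genes. Leaving out a library gave 0 to 451 calls (0 to 226 higher, 0 to 225 lower), and with GC and length correction 0 to 824 (0 to 411, 0 to 413), of which 205 (115 lower) came without DMSO replicate 1. Without DMSO replicate 1 there were 236 calls, 144 of them shared, and without DMSO replicate 2 there were 451, of which 225 were shared. edgeR called 0 without N_12 replicate 1 and 0 without N_12 replicate 2 (unadjusted p under 0.05 for 2855 and 2761 genes), also with the correction (2787 and 2962). In these fits a lone library is assumed to vary like the other group, only edgeR was run, and the cause of the loss was not tested. The median log2 fold change of all genes, 0.0092, moved to 0.0561 at most over the scalings.

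Of the 16 list calls, 16, 15 and 14 stood under RLE, upper quartile and total scaling and 16 under limma-voom, but 0 with an estimated correlation, 0 with fry and 0 with GC and length correction plus an estimated correlation (2, 14 and 3 at an unadjusted p under 0.05). In that order the adjusted p-values were 0.314, 0.0861 and 0.330 for G1/S and replication, 0.52, 0.326 and 0.472 for mitosis, and 0.314, 0.0756 and 0.330 for glycolysis and hypoxia. Over the libraries left out they ranged from 2.70e-08 to 0.152 for mitosis, 2.00e-06 to 0.000124 for G1/S and 7.85e-57 to 4.22e-47 for glycolysis and hypoxia, and 11 to 15 lists were called. The ER chaperone call ended without DMSO replicate 1 (0.223) without either N_12 library (0.0516 and 0.0983), with library totals (0.0633) and with GC and length correction (0.0527), the mitochondrially encoded call without DMSO replicate 1 (0.0562) and without N_12 replicate 1 (0.435), and the YAP and TGF-beta call without N_12 replicate 1 (0.0622). The NF-kB call ended without any 1 library (0.0781 to 0.183), with upper quartile scaling (0.0502), with library totals (0.0578) and without a filter (0.0515). Although limma-voom kept the list calls, it called 0 genes in the G1/S, mitosis, ribosome biogenesis, ER chaperone, oxidative phosphorylation and mitochondrially encoded lists. The epithelial list became called, lower, with GC correction (0.0484), GC and length correction (0.0225), that correction plus the block (0.0323) and without N_12 replicate 2 (0.0324; 0.0324 to 0.451 over the libraries left out). The direction of the adhesion and migration list reversed, without a call, under library totals (0.919), the replicate block (0.943), limma-voom (0.955) and without DMSO replicate 1 (0.963; range 0.826 to 0.964). Directions of lists that camera did not call in any fit reversed as well, for endothelial markers without a filter (0.975) and over the libraries left out (0.353 to 0.963), nilotinib kinases with the stricter filter (0.966), p53 targets (0.200 to 0.668) and anti-apoptotic genes (0.417 to 0.963). Genes not called changed sign when a library was left out, SNAI1 from -0.16 to 0.023, CDKN1A from -0.11 to 0.25, VWF from -0.57 to 0.99 and EGFL7 from -0.12 to 0.18, and EGFL7 with GC and length correction (-0.0075) and with that plus the block (-0.0077). Of the 87 called genes among the 110 tested genes named in the text, 33 lost their calls without robust dispersions, 30 with limma-voom, 42 with the block plus GC and length correction, 24 without DMSO replicate 1, 16 without DMSO replicate 2 and all 87 without either N_12 library. THBS1, AP1M2, NDUFA4 and BMF lost theirs with library totals, THBS1 and NDUFA4 with either GC correction, and 0 with RLE, upper quartile, either filter, the block or DESeq2. Why these moved was not tested. In simulated data with these depths and this spread, 3 of 50 genes changed 1.5-fold were called, so changes of that size mostly cannot be seen with 2 libraries per group.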

Other observations

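The groups and tests in this part were chosen after the values were seen. Of 10 amino acid transporter genes, a choice that was not tested as a group, 4 rose in N_12 by edgeR's adjusted p: SLC6A9 (1.37, SE 0.20, adjusted p = 0.0187), SLC1A4 (1.17, SE 0.18, adjusted p = 0.0247), SLC43A2 (0.98, SE 0.18, adjusted p = 0.0394) and SLC38A1 (0.76, SE 0.15, adjusted p = 0.0479). The other 6 were not called (adjusted p from 0.0542 to 0.727). Limma-voom did not call SLC1A4 (adjusted p = 0.0503), SLC43A2 (0.0727) or SLC38A1 (0.0778). By edgeR with GC and length correction SLC7A1 (adjusted p = 0.0392) and SLC7A11 (0.0219) passed as well. Of the 20 cytosolic aminoacyl-tRNA synthetases, which load tRNAs with amino acids, also not tested as a group, 17 lay above 0. By edgeR 2 were called higher, IARS1 (1.12, SE 0.17, adjusted p = 0.0235) and MARS1 (0.87, SE 0.14, adjusted p = 0.0284). SLC43A2 (adjusted p = 0.148) and SLC38A1 (0.192) lost their calls without DMSO replicate 1, and SLC1A4 (0.0556) and MARS1 (0.0598) without DMSO replicate 2.

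Components of the circadian clock had no common direction. Of 18 tested genes, 9 lay above and 9 below 0. The repressors CRY2 (-1.60, SE 0.19, adjusted p = 0.0102) and PER1 (-1.05, SE 0.16, adjusted p = 0.0232) and the output factors BHLHE40 (-0.82, SE 0.13, adjusted p = 0.0269) and NFIL3 (-0.78, SE 0.14, adjusted p = 0.0365) fell, and the activator NPAS2 rose (0.99, SE 0.13, adjusted p = 0.0162). Limma-voom did not call PER1 (adjusted p = 0.0512), BHLHE40 (0.0514) or NFIL3 (0.0635). BHLHE40 is also induced by low oxygen. It lost its call without DMSO replicate 1 (adjusted p = 0.0901), as did NFIL3.

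The fall of glycolysis and hypoxia genes was weighed first. Neither the GC and length trends of the libraries nor the choice among 4 scalings accounts for it. After correction for GC content and length the list median was -0.94 (95% bootstrap interval over genes -1.32 to -0.74, from -0.90 before). Little could move there, since fold changes followed GC content (Spearman's rho 0.00966) and length (0.131) only weakly across genes. Over the scalings the value closest to 0 was -0.86. These scalings moved the median of all genes to 0.0561 at most, so they could not test a larger shift. HIF1A mRNA, whose protein drives these genes, did not fall with them (0.81, SE 0.23, adjusted p = 0.121). HIF protein was not measured, so this value does not decide whether HIF activity changed. Lower oxygen or a denser, more depleted state of the DMSO cultures at harvest cannot be told apart from an action of N_12, because each culture state would coincide with the treatment; the ATF4 median of 0.37 (0.26 to 0.58) runs against nutrient depletion in DMSO only if N_12 itself leaves ATF4 alone. A lower HIF and glucose response under N_12 is a hypothesis, and oxygen and cell density at harvest would need to be known to test it.

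The fall of ribosomal protein genes was the second pattern. Their median stayed at -0.53 (-0.61 to -0.44) after GC and length correction, from -0.64, so part but not most of it follows those trends. A general loss of short abundant transcripts was weighed with 10000 sets of other genes matched on length and expression. Their medians centred on -0.18 (95% of sets from -0.27 to -0.13), all of them above the ribosomal proteins. The matched sets lay below 0 themselves, against a median of 0.0092 for all genes, so part of the fall may be shared with such transcripts. The comparison argues only against such a loss accounting for the whole fall, and only as far as the match goes. The matched genes, 268 different ones, had a median length of 1291 and 585 CPM, against 1171 and 791 CPM for ribosomal protein genes. A loss that grows steeply with abundance or shortness is therefore not excluded. A shared fall of translation genes with a TOP motif, the element through which mTOR controls translation, stays open: 16 such genes had a median of -0.23 (-0.45 to -0.09) and edgeR called 0 of them (7 at an unadjusted p under 0.05, 4 called by DESeq2, 0 by limma-voom). A specific effect of N_12 on ribosomal protein transcripts may remain, and pseudogene copies in the counting were not examined.

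The third pattern concerned read-through genes, of which 5 were called among 91 tested (5.49%, against 2.23% of other genes, a difference that did not pass Fisher's exact test, two-sided, p = 0.0541). Of the wider set of 423 tested genes that share most of their exon bases with another gene, 18 were called (odds ratio 1.99 against other genes, Fisher's exact test, two-sided, p = 0.0109). The 5 read-through genes were CORO7-PAM16 and ISY1-RAB43, both higher, and PTGES3L-AARSD1 (-1.75), EFNA4-EFNA3 (-1.69) and MIA-RAB4B, all lower, the last with 1.05 and 1.09 CPM in DMSO and 0 in both N_12 libraries. EFNA4-EFNA3 lost its call without DMSO replicate 1 (adjusted p = 0.0553). Summed with the genes that share their exons, these 5 changed by a median absolute log2 value of 0.283, against 1.75 for the read-through genes alone (also with MIA-RAB4B at the bound that 3 counts per library allow). This decides nothing, because a change of the read-through genes alone, with their partners as in DMSO, would have moved the sums by a median of only 0.358, so a different assignment of reads between overlapping genes cannot be told apart from a change in read-through by N_12. CORO7 stood at 23.4 ± 0.814 CPM in DMSO and 8.53 ± 3.71 CPM in N_12 (-1.45, adjusted p = 0.0662), while CORO7-PAM16 rose. Over all 91, replicates of read-through genes differed 2.09 times as much as those of other genes at the same expression (95% bootstrap interval 1.60 to 3.03), so unstable assignment of reads may contribute to these calls and stays open.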
